A study of Mus musculus with 178 samples.

How the data were processed

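RNA was measured by sequencing in 178 libraries of mouse tibialis anterior muscle (137 wild type, 41 CCR2KO). Per the labels' protocols, muscle was injected with notexin and digested, and cells were sorted by flow cytometry before RNAzol extraction. The gates were CD45+/CD31- for inflammatory cells, CD45-/CD31+ for endothelial cells, and CD45-/CD31- with alpha-7 integrin and VCAM for myogenic progenitors. FAP were the CD45-/CD31- cells carrying the EGFP reporter of PDGFRa, and pericytes the CD45-/CD31-/Sca1- cells carrying the DsRed reporter of NG2. Genes that set a gate are no finding between gates, but marker lists hold some (Ptprc, Pecam1, Itga7, Vcam1, Cspg4, Pdgfra and Ly6a) and count them. Stranded mRNA libraries were read as paired ends of 43 bases on an Illumina sequencer, per the labels' protocols.

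The values are raw read counts per gene symbol, as the authors deposited them in 9 tables, 1 per population and genotype. Per the submitters' processing notes, the tools were bcl2fastq, Bowtie and STAR and the genome build was mm10. Their versions and roles, the counting program, its strand setting and the annotation are not given in the sources used here. Counts of genes with near-identical copies and of overlapping or antisense genes are therefore uncertain. The tables held 24421 gene symbols, of which 23376 were found in GENCODE M21, used here for coordinates only (GRCm38). The entries for reads in no feature and ambiguous reads (0.24% to 1.78% per library) name no gene and stayed out of library totals and tests.

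Population, genotype, day and replicate number came from the titles, and columns were matched to libraries by name. For 2 EC columns the name gave the group and not the library, and these carry no number or code. Fits that drop libraries by code kept them, though their labels hold another day or R52. Among the other libraries, codes in the labels name another day than the title in 14, and the title was used. Some codes hold R52, and its meaning is not given in the sources used here. Checked for duplicates, none of 169 pairs within a group came near sampling noise (lowest chi-square per gene 2.67, median 118). Pairs of total muscle that share a code lay between 2.67 and 25.9. PCR copies count as reads, so depth bounds counting error only.

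Tests used edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with the design, trended dispersion, quasi-likelihood F test), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes are from this test unless DESeq2 is named. Wild-type days were fitted per population with 1 mean per day and a shared spread, so a day with 1 library uses the spread of the others. Genotypes were compared in FAP and EC with 1 mean per genotype and day, and across days with day as an added factor on the days both genotypes have. The population comparison used days 0, 1, 2, 3, 5 and 10, and enrichment also needed a log2 fold change above 1. Standard errors of log2 fold changes come from the same fits. CPM beside a log2 fold change are TMM-scaled within that fit, and Vegfa by day, marker levels by day and the sources of ligands are scaled over all libraries they cover, so the same group can differ slightly between them.

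There were 38 gene lists of 425 genes, 421 of them in the tables, fixed before the data were examined, as were the comparisons, the fits and all alternatives but 4. Lists were tested with limma 3.58.1 (camera on log2 CPM with a prior count of 2), once with a preset correlation of 0.01 and once with an estimated correlation. Both p-values were adjusted over the lists of a comparison. Called members were counted over all genes and again with p-values adjusted over the list alone. Several marker lists hold genes that more than 1 cell type expresses.

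The genes named follow a rule fixed with the lists. Named genes were up to 4 called members per list with the largest absolute log2 fold change and at least 10 CPM in the higher group, and the 6 highest and 6 lowest called genes at that level whose groups of libraries did not overlap. Between populations and genotypes over several days, the sign had to be the same on every day. Up to 8 enriched ligands per population, Vegfa everywhere and Ccr2 in the genotype comparisons were added, and Gm, Rik, ribosomal and mitochondrial genes left out. The text gives a part of the genes so selected. Lars2 and Ccr9 in FAP, Ide in EC, Lars2, Ide and Alad in MP and the genes followed by day in the closing observations were chosen after their values were seen. Some genes that passed are not reported here.

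Alternatives were RLE scaling, no filter on low counts, the replicate number as a block (in the libraries whose title holds one), the R52 code as a covariate or as a reason to leave a library out, leaving out libraries whose code names another day, fitting the compared groups alone, DESeq2 1.42.0, a preparation block in limma, and leaving out each library in turn. Refits without a library and over other splits of the libraries kept the dispersion trend of the full fit, and re-estimating it moved the EC count at day 3 without undamaged library 1 from 514 to 518. The gene test ran on counts simulated from real means and library sizes with only 200 genes changed. In FAP at day 3 between genotypes (15391 genes) it recovered 12% of 100 genes changed 2-fold and 74% of 100 changed 4-fold, and 5.49% of its calls were unchanged genes. Recovery of 2-fold and 4-fold changes was 87% and 100% in FAP across days (14654 genes) and 10% and 64% in EC at day 3 (15603 genes). It was 0% and 0% in pericytes and 0% and 1% in MP (4954 real calls) at day 3. It was 0% and 13% for the response and 2% and 35% in EC of CCR2KO at day 1. In inflammatory cells at day 3 it was 2% and 47%, with 9.26% of calls unchanged. For the FAP enrichment (17134 genes) 99% of 4-fold and of 8-fold changes were recovered, with 28 unchanged genes among 226 calls (12.4%). The shares of 9.26% and 12.4% exceed the 5% aimed at. Single values of Vegfa were compared with exact two-sided permutation tests. Raw reads were not used here.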

Results

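Gene counts were analysed for 178 RNA libraries of mouse tibialis anterior muscle, undamaged or 1 to 14 days after injection of notexin, a snake venom phospholipase that destroys muscle fibres and spares their stem cells. Cells were sorted into inflammatory cells (27 libraries), myogenic progenitors (MP; 16 wild-type and 9 CCR2KO), endothelial cells (EC; 31 and 14), fibro-adipogenic progenitors (FAP; 32 and 18) and pericytes (10), and total muscle gave 21 libraries. Undamaged muscle counts as day 0, and a group of 1 population, genotype and day held 1 to 6 libraries. Gene counts summed to between 1236809 and 37740952 per library (median 13736700), and reads assigned to no gene made up 3.1% to 57% of assigned and unassigned counts together (median 7.6%). By correlation with the mean profile of each population, 152 of 157 sorted libraries stood closest to their own. The exceptions were EC day 1 library 3 and EC day 3 library 5, closest to FAP, MP day 2 library 1 and MP day 3 library 1, closest to inflammatory cells, and MP day 10 library 1, closest to pericytes, all wild type. Log2 fold changes are given with their standard error (SE) and levels in counts scaled to a library total of 1000000 (CPM) with the standard deviation (SD) over libraries. The labels do not say which libraries came from separate animals, so p-values measure the spread between these libraries.

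The targeted gene, Ccr2 (chromosome 9, 124101950 to 124113557), encodes the receptor that brings monocytes from blood into damaged tissue. Its counts served to check the genotype labels. In CCR2KO libraries its median was 0 CPM in FAP (18 libraries, 13 with 0 counts) and MP (9 libraries, 6 with 0 counts). It was 0.0831 CPM in CCR2KO EC (14 libraries, 5 with 0 counts). Wild-type medians were 0.938 CPM in FAP (32 libraries, 1 with 0 counts), 4.58 CPM in MP (16 libraries) and 5.47 CPM in EC (31 libraries, 1 with 0 counts), against 278 CPM in wild-type inflammatory cells (27 libraries, 84.9 to 669 CPM) and 20.8 CPM in total muscle (21 libraries). At least 1 CPM was found in 4 libraries labelled CCR2KO: EC day 7 library 3 (7.73 CPM, 127 counts), FAP day 7 library 1 (1.82 CPM, 20 counts), MP undamaged library 1 (2.68 CPM, 17 counts) and MP day 10 library 1 (3.26 CPM, 40 counts). The code of the last, 6F, is also that of 2 wild-type libraries of day 10, EC library 1 and FAP library 1. Ccr2 was low in wild-type FAP too, so its absence there is a weaker check of the label than in MP or EC. The deleted part of the gene is not given in the sources used here.

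**Figure D1:**
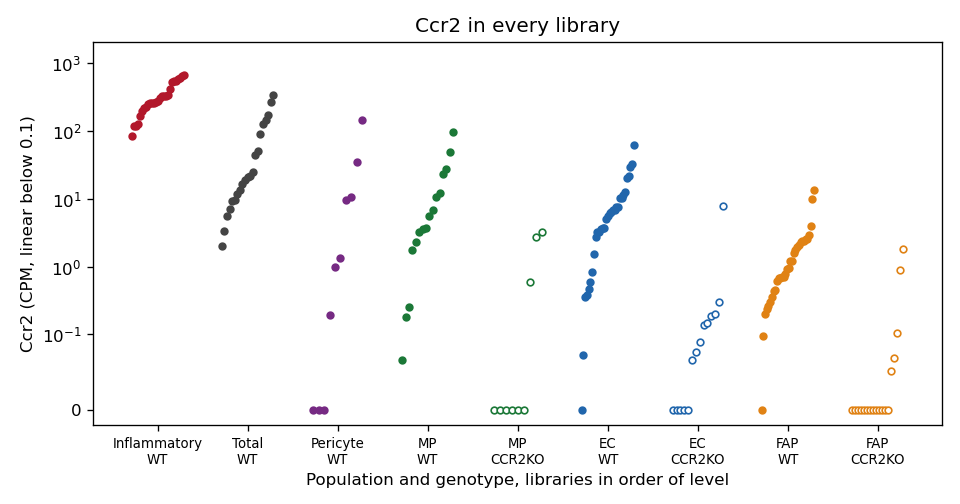
Ccr2 in CPM (vertical axis, log scale above 0.1) in each library, by population and genotype (filled wild type, open CCR2KO). The highest CCR2KO library, in EC, stands at 7.73 CPM, above the wild-type EC median of 5.47 CPM, and the lowest inflammatory library at 84.9 CPM.

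The populations were first set against each other in wild-type libraries, each as the mean over days 0, 1, 2, 3, 5 and 10 against the mean of the other 4. Inflammatory cells (19 libraries against 67) were marked by myeloid genes. Adgre1, the macrophage antigen F4/80, stood at 987 ± 374 CPM (SD), a log2 fold change of 6.94 ± 0.41 (SE, adjusted p = 4.34e-23), and Cd74 at 7650 ± 7990 CPM (7.20 ± 0.42). Their secreted ligands included the chemokines Ccl3 (6.93 ± 0.53) and Ccl6 (6.82 ± 0.42), the cytokine oncostatin M, Osm (6.97 ± 0.40), and Il10, an anti-inflammatory cytokine (7.40 ± 0.63). Vegfa was enriched by 1.34 ± 0.26 (adjusted p = 7.89e-06) over these days, day 10 from 1 library (256 CPM). Before injury it stood at 26.8 CPM against 124 in FAP and 89.8 in MP. Enrichment with a log2 fold change above 1 was called for 2932 of 17134 genes. Among them were all 6 leukocyte markers, 11 of 12 macrophage markers, all 8 T and NK cell markers and 5 of 6 dendritic cell markers (6, 11, 8 and 5 adjusted over the list alone, camera adjusted p = 2.55e-07, 2.98e-08, 2.28e-06 and 0.000134). With an estimated correlation, adjusted p = 0.106, 0.106, 0.106 and 0.112, in that order.

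MP (12 libraries) were marked by transcription factor genes of the muscle lineage, Pax7 at 314 ± 328 CPM (8.38 ± 0.43, adjusted p = 9.71e-25), Myf5 (8.64 ± 0.43) and Myod1 (7.98 ± 0.47). Among ligands, the neurotrophic factor Gdnf stood at 25.8 ± 26.6 CPM (4.85 ± 0.37). Of 17134 genes 1747 were enriched, with all 8 satellite cell markers, 6 of 8 quiescence genes and 8 of 10 differentiation genes (8, 6 and 8 adjusted over the list alone, camera adjusted p = 2.41e-14, 3.59e-06 and 1.32e-08). An estimated correlation gave an adjusted p of 0.000841, 0.0075 and 0.0117, in that order. Mature myofibre genes were enriched in 11 of 12 (11 adjusted over the list alone, camera adjusted p = 2.25e-07), skeletal actin, Acta1, at 1900 ± 4670 CPM (17600 in day 10 library 1, the one closest to pericytes). Under an estimated correlation the adjusted p was 0.241.

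EC (22 libraries) were marked by the junction gene Cdh5 at 3170 ± 1190 CPM (7.29 ± 0.35, adjusted p = 7.75e-28), Kdr (6.78 ± 0.38) and the Notch ligand Dll4 (7.03 ± 0.30). Their ligands included endothelin, Edn1, at 94.1 ± 44.9 CPM (5.07 ± 0.34), and Pdgfb, which recruits mural cells (4.68 ± 0.23). Of 17134 genes 2518 were enriched, with all 11 endothelial markers, 7 of 10 VEGF family and receptor genes and 8 of 9 angiogenic endothelial genes (11, 7 and 8 adjusted over the list alone, camera adjusted p = 5.73e-23, 0.000107 and 4.09e-09). Estimating the correlation gave an adjusted p of 0.000569, 0.011 and 4.11e-05, in that order.

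Pericytes (10 libraries) were marked by the smooth muscle genes Myh11 at 5050 ± 4610 CPM (7.61 ± 0.45, adjusted p = 8.99e-23) and Acta2 at 12400 ± 8370 CPM (6.28 ± 0.30). Their ligands included Fgf1 (4.82 ± 0.31). Of 17134 genes 2157 were enriched, with all 9 pericyte and smooth muscle markers and all 5 Schwann cell markers (9 and 5 adjusted over the list alone, camera adjusted p = 2.76e-15 and 7.38e-09). This became an adjusted p of 0.00969 for both with an estimated correlation. The glial transcription factor gene Sox10 stood at 374 ± 359 CPM (8.09 ± 0.43). Without day 3 library 2 the count was 1072.

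FAP (23 libraries) were marked by matrix and complement genes. Col3a1 stood at 31600 ± 20200 CPM (5.03 ± 0.48, adjusted p = 8.83e-14), C3, the central complement component, at 2720 ± 1510 CPM (4.66 ± 0.46) and Pdgfra, whose reporter set the gate, at 1130 ± 574 CPM (5.99 ± 0.54). Among ligands, Wnt2 (6.81 ± 0.56), Fgf7 (5.58 ± 0.60) and the chemokine Cxcl5 (5.68 ± 0.59) were enriched. Of 17134 genes 3014 were enriched, with all 10 stromal progenitor markers, all 12 fibrillar matrix genes, all 9 basement membrane genes and all 8 complement genes (10, 12, 9 and 8 adjusted over the list alone, camera adjusted p = 4.22e-10, 4.22e-10, 1.31e-08 and 4.6e-07). The adjusted p was 0.0858 for each with an estimated correlation. Secreted ligands were enriched in 95 of 161 (96 adjusted over the list alone, camera adjusted p = 7.43e-08). At an estimated correlation the adjusted p was 0.18.

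Sources of secreted ligands were counted from the mean over the same 6 days, with 10 CPM as the floor. Of 162 listed ligands in the tables, 139 reached the floor in at least 1 sorted population, 103 of them (74.1%) in more than 1, 44 in all 5 and 36 in 1. FAP held 101 ligands at the floor and were the only source of 12, pericytes 93 and 6, EC 88 and 4, inflammatory cells 78 and 13, and MP 76 and 1. Single-source ligands were Il10 in inflammatory cells (127 CPM against 5.67 CPM in MP, the next), Vegfc in EC (34.2 against 7.63 CPM in FAP), Sema3a in MP (15.3 against 9.57 CPM in pericytes) and Wnt5a in FAP (26.5 against 4.32 CPM in pericytes). Shared ligands included Vegfa, Cxcl12 (1630 CPM in EC, 929 in FAP) and Igf1 (275 CPM in FAP, 166 in inflammatory cells). Vegfa stood at 130 CPM in inflammatory cells (day 10: 1 library), 67.6 in MP, 56.4 in FAP, 31.5 in pericytes and 19.5 in EC. The order differed before injury and at day 3 (highest in pericytes, 68.6 ± 62.6 CPM). The number with more than 1 source was 123 at a floor of 5 CPM, 93 at 20 and 151 at 1. These levels have no test, and RNA carried over from other populations counts toward a source.

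**Figure D2:**
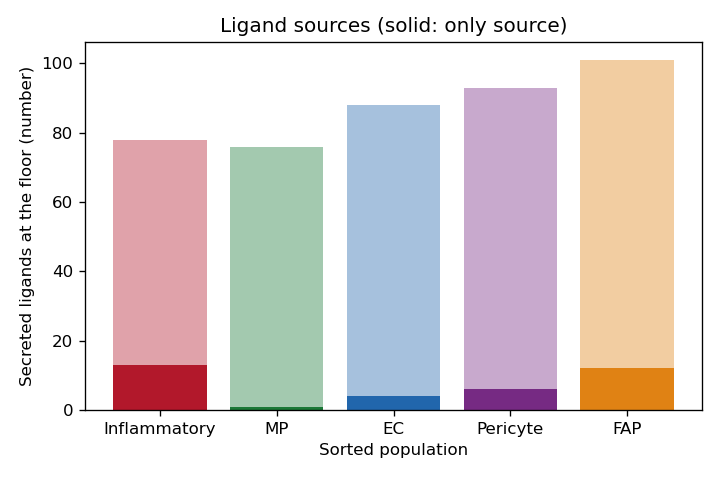
Number of secreted ligands at 10 CPM or more in each sorted population, solid where it was the only source. FAP reach 101 ligands and MP 76.

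The first set of comparisons asked how each sorted population and the whole muscle stood 3 days after notexin against undamaged muscle. Among the CD45+ cells, the macrophage genes Gpnmb, Spp1 and Trem2 rose and B cell markers fell. Gpnmb, a glycoprotein of lysosome-rich macrophages, rose from 10.7 ± 2.83 to 9790 ± 2800 CPM (SD, n = 2 and 4), a log2 fold change of 9.84 ± 1.12 (SE, adjusted p = 1.46e-05). Spp1, which encodes the secreted phosphoprotein osteopontin, rose by 10.00 ± 1.49 to 13200 ± 4530 CPM, and Trem2, a lipid-sensing receptor of macrophages, by 5.15 ± 0.78 to 754 ± 187 CPM (highest adjusted p of the pair, 0.000155). In all, 2607 of 15016 genes passed the threshold, 1063 higher and 1544 lower at day 3.

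Of 12 resident and repair macrophage markers tested, 4 rose and 2 fell (4 up and 2 down adjusted over the list alone, camera adjusted p = 0.00263). The estimated correlation gave an adjusted p of 0.621. The members that fell were the resident macrophage receptors Lyve1 (-6.22 ± 1.07) and Cd163 (-5.50 ± 1.00). All 4 B cell markers and 4 of 8 T and NK cell markers fell (4 and 4 down adjusted over the list alone, camera adjusted p = 4.33e-06 and 0.0205), among them the T cell receptor chain gene Cd3g (-5.39 ± 1.44) and the co-receptor gene Cd8a (-5.10 ± 1.08). Camera with an estimated correlation gave an adjusted p of 0.141 and 0.66, in that order. Of MHC class II genes 3 of 6 fell, and of dendritic cell markers 3 of 6 (5 and 6 down adjusted over the list alone, camera adjusted p = 0.0233 and 0.0131). For an estimated correlation the adjusted p was 0.625 and 0.536, in that order. The antigen-presentation gene Cd74 stood at 3270 ± 1830 against 13400 ± 7320 CPM (-2.04 ± 0.65), and Ccr7, a lymph-node homing receptor, at -4.41 ± 0.97. Of 7 neutrophil markers 4 fell (1 up and 4 down adjusted over the list alone), led by the calgranulin gene S100a9 (-5.75 ± 1.22, adjusted p = 0.00274), without a call for the list (camera adjusted p = 0.282).

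Interferon response genes rose in 8 of 10 (10 up adjusted over the list alone, camera adjusted p = 5.58e-06). With the correlation estimated, adjusted p = 0.536. The interferon regulatory factor gene Irf7 rose from 59.5 ± 17.1 to 815 ± 372 CPM (3.78 ± 1.10, adjusted p = 0.0216) and Ifit3 by 4.33 ± 1.22. Glycolysis genes rose in 6 of 11 (7 up adjusted over the list alone, camera adjusted p = 0.000624), Pgam1 by 2.68 ± 0.68 and Pkm, the pyruvate kinase gene, by 1.86 ± 0.47. Adjusted p = 0.536 with an estimated correlation. Among 12 matrix proteases 4 rose and 1 fell (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.0107). With an estimated correlation, adjusted p = 0.536. The membrane-bound metalloproteinase gene Mmp14 rose to 269 ± 52.6 CPM (4.46 ± 0.66) and Mmp9, a gelatinase gene of granulocytes, fell to 17.6 ± 11.3 CPM (-3.63 ± 0.91). Hgf, a growth factor for muscle stem cells, rose to 30.8 ± 18.3 CPM (3.44 ± 0.88, adjusted p = 0.00977). Genes of tissue outside the gate also moved, as 6 of 12 mature myofibre genes fell (10 down adjusted over the list alone, camera adjusted p = 0.000324), the creatine kinase gene Ckm to 2.05 ± 0.767 from 13.3 ± 6.67 CPM. An estimated correlation gave an adjusted p of 0.536. The SD of the undamaged pair exceeded its mean for Lyve1, Cd163, Cd3g and Ccr7. Without undamaged library 2 the count was 727. With the 6 compared libraries alone in the fit it was 1429. Xist stood at 426 and 747 CPM in the undamaged pair and under 2 CPM in 3 of 4 libraries at day 3, so sex may differ between the days. With Xist as a covariate, chosen after seeing the data, the count was 508, Gpnmb, Spp1 and Trem2 among them.

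In the myogenic progenitor (MP) gate, Pax7 and Calcr fell and Birc5, Myod1 and Myog rose at day 3. Pax7, the transcription factor gene of satellite cells, fell from 924 ± 146 to 38.8 ± 4.51 CPM (SD, n = 3 and 2), a log2 fold change of -4.57 ± 0.71 (SE, adjusted p = 0.0012), and Calcr, a receptor that keeps satellite cells quiescent, fell by 9.14 ± 1.26. Birc5, a chromosomal passenger gene of mitosis, rose by 6.61 ± 0.64 to 266 ± 105 CPM, and Myod1 and Myog, transcription factor genes of myogenic commitment, rose by 3.10 ± 0.51 and 4.32 ± 1.29 (highest adjusted p of the 3, 0.0251). Of 15452 genes tested, 4954 passed, 2730 higher and 2224 lower.

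All 8 satellite cell quiescence genes fell (8 down adjusted over the list alone, camera adjusted p = 3.54e-06), including the signalling antagonist genes Chrdl2 (-7.91 ± 0.90) and Spry1 (-5.17 ± 0.55). Under an estimated correlation the adjusted p was 0.0411. Of 8 satellite cell markers 6 fell and 1 rose, and 5 of 10 differentiation genes rose (2 up and 6 down and 7 up adjusted over the list alone, camera adjusted p = 0.00471 and 0.00471). Estimating the correlation gave an adjusted p of 0.589 and 0.577, in that order. Cell cycle genes rose, 11 of 12 mitosis genes and 9 of 10 S phase genes (12 and 9 up adjusted over the list alone, camera adjusted p = 7.09e-08 and 1.52e-06), Mcm5 of the replicative helicase by 4.46 ± 0.47. This became an adjusted p of 0.494 for both with an estimated correlation. Glycolysis genes rose in 7 of 11 and oxidative phosphorylation genes in 9 of 12 (8 and 9 up adjusted over the list alone, camera adjusted p = 0.000272 and 0.000973), Gapdh reaching 5490 ± 53.9 CPM from 293 ± 97.4. The adjusted p was 0.577 and 0.589, in that order with an estimated correlation. Immediate early and heat shock genes fell in 8 of 11 and basement membrane genes in 6 of 9 (8 and 8 down adjusted over the list alone, camera adjusted p = 0.000124 and 0.000905). At an estimated correlation the adjusted p was 0.589 and 0.577, in that order. Egr1 stood at 361 ± 112 against 14800 ± 2570 CPM and Fos at 815 ± 586 against 14900 ± 1390 CPM. The laminin gene Lama2 fell by 5.10 ± 0.62 and the collagen gene Col4a1 fell by 4.60 ± 0.82.

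Leukocyte genes rose in the same libraries. All 6 leukocyte markers rose, together with 8 of 12 macrophage markers and 5 of 6 MHC class II genes (6, 8 and 6 up adjusted over the list alone, camera adjusted p = 0.00153, 0.00131 and 0.00536). The estimated correlation gave an adjusted p of 0.589, 0.618 and 0.618, in that order. Laptm5 went from 4.31 ± 1.01 to 1540 ± 1500 CPM, and the complement gene C1qb reached 1100 ± 1090 CPM. Of the 2 libraries at day 3, library 1 had a profile closest to the inflammatory population, and the SD of both genes was nearly the size of the mean. Vegfa fell by 2.22 ± 0.64 to 22.7 ± 1.31 CPM (adjusted p = 0.0218). The count was 3040 without undamaged library 1 and 3265 and 2130 without day 3 libraries 1 and 2, each left out alone. Undamaged libraries 1 and 2 and day 4 library 1 had over 40% of counts outside genes, and without them 593 genes were called. All 3 undamaged libraries and neither at day 3 have a code with R52, and with that code as a covariate, estimated on other days, the count was 2793.

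In CD31+ endothelial cells (EC) at day 3, Birc5 and Irf7 rose and the VEGF receptor genes Flt1 and Kdr fell. Birc5 rose from 1.18 ± 0.966 to 29.8 ± 13 CPM (SD, n = 4 and 5), a log2 fold change of 4.57 ± 0.85 (SE, adjusted p = 0.00363), and Irf7 from 95.7 ± 33.4 to 890 ± 556 CPM (3.22 ± 0.58, adjusted p = 0.00306). Flt1 and Kdr fell by 1.17 ± 0.34 and 1.14 ± 0.35, to 702 ± 214 and 598 ± 214 CPM (highest adjusted p, 0.0499). The threshold was passed by 1020 of 15603 genes, 742 higher and 278 lower.

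All 12 mitosis genes and 3 of 10 S phase genes rose (12 and 5 up adjusted over the list alone, camera adjusted p = 2.3e-12 and 0.0133), the cyclin genes Ccnb1 by 4.18 ± 0.83 and Ccnb2 by 3.78 ± 0.77. Camera with an estimated correlation gave an adjusted p of 0.312 and 0.437, in that order. Interferon response genes rose in 6 of 10 (9 up adjusted over the list alone, camera adjusted p = 4.32e-07), the antiviral gene Oasl2 by 2.73 ± 0.43 and Mx1 by 4.25 ± 1.17. For an estimated correlation the adjusted p was 0.333. Of 10 VEGF family and receptor genes, 1 rose and 3 fell (1 up and 3 down adjusted over the list alone, camera adjusted p = 0.0632). Pgf, placental growth factor, rose by 2.22 ± 0.53, and Vegfc, the lymphatic growth factor, fell by 1.64 ± 0.34. Of 11 endothelial markers 2, Flt1 and Kdr, fell (2 down adjusted over the list alone, camera adjusted p = 0.414). Basement membrane genes rose in 3 of 9 and glycolysis genes in 4 of 11 (4 and 5 up adjusted over the list alone, camera adjusted p = 0.0133 and 0.00255), Lamb1 by 1.37 ± 0.31 and Gapdh by 2.01 ± 0.46. With the correlation estimated, adjusted p = 0.407 and 0.333, in that order. The tip cell gene Esm1 fell by 2.48 ± 0.58 to 5 ± 4.19 CPM and Bmp6, which signals to iron metabolism, by 2.01 ± 0.32 to 38.4 ± 13 CPM (adjusted p = 0.000971).

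Markers of other cells moved in these libraries. The macrophage genes Trem2 (5.97 ± 1.37) and Gpnmb rose, Gpnmb from 25.6 ± 44.3 to 823 ± 744 CPM, with 1 of 6 leukocyte markers called (5 up adjusted over the list alone, camera adjusted p = 1.15e-05). Adjusted p = 0.333 with an estimated correlation. The myogenic gene Myog rose to 16.3 ± 13.4 CPM (6.54 ± 1.42), and the smooth muscle gene Acta2 fell by 1.78 ± 0.54. Of 8 satellite cell markers 4 fell and of 5 Schwann cell markers 2 (4 and 3 down adjusted over the list alone, camera adjusted p = 0.0133 and 0.00219). With an estimated correlation, adjusted p = 0.407 and 0.333, in that order. The count was 514, 263 and 636 without undamaged libraries 1, 3 and 4 and 539, 1602, 635, 483 and 1598 without day 3 libraries 1, 2, 3, 4 and 5, each left out alone. It was 2021 without both libraries closest to FAP, 1909 by DESeq2 and 258 with the compared libraries alone in the fit.

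Pericytes, gated by NG2 in a reporter line, gave few calls at day 3. Spp1 rose from 4.45 ± 0.785 to 1780 ± 915 CPM (SD, n = 2 and 2), a log2 fold change of 8.64 ± 1.05 (SE, adjusted p = 0.0014). The other 5 genes that rose were macrophage and phagocyte genes, each at an adjusted p of 0.0499. They were C1qa (9.20 ± 1.61), Cd68 (8.83 ± 1.55), Fcgr1 (to 291 ± 134 CPM, from 2 counts in the undamaged pair), Mpeg1 (8.29 ± 1.45) and Myo1f (10.64 ± 1.88). The threshold was passed by 6 of 15127 genes, 6 higher and 0 lower, with 1524 at an unadjusted p under 0.05. In set tests, none of 6 leukocyte markers, 1 of 12 macrophage markers and none of 12 mitosis genes were called over all genes (6, 8 and 12 up adjusted over the list alone, camera adjusted p = 5.8e-16, 1.03e-12 and 2.67e-06). An estimated correlation gave an adjusted p of 0.207, 0.207 and 0.541, in that order. Vegfa stood at 79.6 ± 72.1 against 15.5 ± 12.5 CPM (2.35 ± 1.41, adjusted p = 0.596). Library 1 of day 3 held the lowest total of all libraries. The count was 0 and 0 without undamaged libraries 1 and 2 and 345 and 6727 without day 3 libraries 1 and 2, each left out alone. DESeq2 called 834 genes, 465 higher and 369 lower, and other scaling (RLE) factors in edgeR 39.

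In fibro-adipogenic progenitors (FAP), the PDGFRa-reporter cells of the muscle stroma, Timp1, Tnc and Postn rose at day 3 and Gsn fell. Timp1, a metalloproteinase inhibitor, rose from 30.1 ± 17.1 to 816 ± 562 CPM (SD, n = 3 and 6), a log2 fold change of 4.76 ± 0.66 (SE, adjusted p = 1.98e-05), and Tnc and Postn, matrix proteins of healing tissue, rose by 3.69 ± 0.65 and 2.60 ± 0.65. Gsn, an actin-severing protein abundant in resting stroma, fell from 42900 ± 4250 to 4460 ± 2610 CPM (-3.27 ± 0.40, adjusted p = 5.4e-06). Vegfa fell from 119 ± 38.9 to 38.3 ± 17.8 CPM (-1.64 ± 0.38, adjusted p = 0.00323). The threshold was passed by 2914 of 15205 genes, 1709 higher and 1205 lower.

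Fibrillar matrix genes rose in 8 of 12, and matrix proteases rose in 5 and fell in 1 of 12 (9 up and 7 up and 1 down adjusted over the list alone, camera adjusted p = 3.55e-06 and 0.00519). Under an estimated correlation the adjusted p was 0.0684 and 0.129, in that order. The proteoglycan gene Bgn reached 10800 ± 3580 CPM (2.40 ± 0.38) and Adam12, a metalloproteinase of activated stroma, rose by 3.83 ± 0.44. All 12 mitosis genes and 7 of 10 S phase genes rose (12 and 7 up adjusted over the list alone, camera adjusted p = 1.34e-13 and 1.74e-05), Birc5 by 5.17 ± 0.75. Estimating the correlation gave an adjusted p of 0.0684 and 0.129, in that order. Of 10 stromal progenitor markers 6 fell (6 down adjusted over the list alone, camera adjusted p = 4.43e-05), Dcn, the decorin gene, by -1.80 ± 0.38 and Pi16 by -2.04 ± 0.58. This became an adjusted p of 0.0722 with an estimated correlation. TGF-beta family genes fell in 6 of 13 (1 up and 9 down adjusted over the list alone, camera adjusted p = 0.000675), the bone morphogenetic protein genes Bmp2 by -3.31 ± 0.61 and Bmp4 by -2.18 ± 0.36. The adjusted p was 0.0684 with an estimated correlation. Chemokine genes rose in 8 of 13 and fell in 1, and 9 of 10 interferon response genes rose (8 up and 1 down and 9 up adjusted over the list alone, camera adjusted p = 0.000392 and 2.64e-08). At an estimated correlation the adjusted p was 0.129 and 0.0994, in that order. Cxcl12, which retains leukocytes and stem cells, rose to 1440 ± 556 CPM (2.26 ± 0.31), Cxcl9, a T cell attractant, by 4.07 ± 1.03, and Ifit3 from 14.4 ± 2.32 to 297 ± 53.9 CPM (4.37 ± 0.74). Among 13 Wnt and Notch genes 2 rose and 4 fell (2 up and 6 down adjusted over the list alone, camera adjusted p = 0.121), with Wisp1 at 3.48 ± 0.58 and Wnt5a at -1.39 ± 0.27. The complement gene C7 fell from 879 ± 327 to 36 ± 27.3 CPM (-4.61 ± 0.72).

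Markers of other cells rose at lower levels. All 6 leukocyte markers rose, as did 7 of 12 macrophage markers, 5 of 6 MHC class II genes and 8 of 10 myogenic differentiation genes (6, 8, 5 and 8 up adjusted over the list alone, camera adjusted p = 1.35e-06, 1.39e-06, 1.74e-05 and 5.13e-06). The estimated correlation gave an adjusted p of 0.0684, 0.0921, 0.111 and 0.0994, in that order. Tyrobp reached 30.2 ± 25.1 CPM and C1qb 50.7 ± 53.9 CPM. The mural cell gene Notch3 rose to 153 ± 114 CPM (3.83 ± 0.56), one of 4 of 9 such markers that rose (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.0677). Without undamaged libraries 2 and 3, each left out alone, the count was 1780 and 1603.

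In total muscle at day 3, Ckm fell, and Myh3 and Ptprc rose. The 2 libraries of each of these days share a code with suffixes A and B, so the spread may lie within 1 preparation. Ckm, the muscle creatine kinase gene, fell from 27800 ± 66.1 to 8070 ± 1540 CPM (SD, n = 2 and 2), a log2 fold change of -1.79 ± 0.25 (SE, adjusted p = 5.34e-06). Myh3, the embryonic myosin heavy chain gene of new fibres, rose from 9.49 ± 1.52 to 1200 ± 60.2 CPM (6.98 ± 0.20, adjusted p = 1.3e-13), and Tmem8c, which encodes the myoblast fusion protein myomaker, rose to 147 ± 6.57 CPM from 1 count in the undamaged pair. Ptprc, the CD45 gene, rose by 5.87 ± 0.35 to 141 ± 34.2 CPM and Ccr2 by 4.65 ± 0.25 to 83.2 ± 16.5 CPM. Vegfa fell from 330 ± 13.9 to 87 ± 24.3 CPM (-1.92 ± 0.31, adjusted p = 2.85e-05). The threshold was passed by 9315 of 14151 genes, 4833 higher and 4482 lower.

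All 12 mature myofibre genes fell, as did all 12 oxidative phosphorylation genes, 6 of 10 hypoxia genes and all 11 endothelial markers (12, 12, 6 and 11 down adjusted over the list alone, camera adjusted p = 4.42e-05, 1.34e-05, 0.0382 and 0.00124). Camera with an estimated correlation gave an adjusted p of 0.381 for each. Myoglobin, Mb, fell by 2.59 ± 0.50 and the endothelial receptor gene Flt1 fell by 1.45 ± 0.18. All 6 leukocyte markers and all 5 T and NK cell markers rose, with 7 up and 1 down of 8 inflammatory monocyte markers and 9 up and 1 down of 12 macrophage markers (6 up, 5 up, 7 up and 1 down and 9 up and 1 down adjusted over the list alone, camera adjusted p = 9.46e-05, 0.0376, 0.0182 and 0.000413). For an estimated correlation the adjusted p was 0.381 for each. Trem2 stood at 82.2 ± 21.1 against 0.342 ± 0.186 CPM and Gpnmb at 702 ± 375 against 3.99 ± 2.06 CPM.

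All 12 fibrillar matrix genes rose, with all 10 S phase genes and 11 of 12 mitosis genes (12, 10 and 11 up adjusted over the list alone, camera adjusted p = 9.46e-05, 1.18e-05 and 2.59e-06), the collagen gene Col3a1 to 1970 ± 354 CPM (2.56 ± 0.26). With the correlation estimated, adjusted p = 0.381 for each. Myogenic differentiation genes rose in 8 of 10 and fell in 2 (8 up and 2 down adjusted over the list alone, camera adjusted p = 0.000484), and Pax7 rose by 2.13 ± 0.27. Adjusted p = 0.381 with an estimated correlation. All 10 interferon response genes and all 6 MHC class II genes rose, with 10 of 13 chemokine genes and 7 of 9 cytokine genes (10 up, 6 up, 10 up and 2 down and 7 up adjusted over the list alone, camera adjusted p = 9.46e-05, 0.000205, 0.0106 and 0.0376). With an estimated correlation, adjusted p = 0.381 for each. Irf7 reached 161 ± 5.28 CPM, and Cxcl10 rose by 6.90 ± 0.76. The insulin-like growth factor genes Igf1 and Igf2 rose by 1.92 ± 0.19 and 3.51 ± 0.19, to 61.6 ± 7.14 and 213 ± 10.1 CPM (highest adjusted p, 1.32e-07).

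The same comparison was made 10 days after notexin. In the MP gate, Tnc and Igf2 stood higher and Chrdl2 and Ret lower than in undamaged muscle. Tnc rose from 10.2 ± 2.42 to 517 ± 335 CPM (SD, n = 3 and 2), a log2 fold change of 5.66 ± 0.58 (SE, adjusted p = 0.005), and Igf2, an insulin-like growth factor gene, from 164 ± 54.7 to 843 ± 1.11 CPM (2.36 ± 0.41, adjusted p = 0.0345). Chrdl2 fell by 4.12 ± 0.73 to 30.2 ± 9.45 CPM and Ret, a receptor tyrosine kinase gene, by 2.62 ± 0.42 (highest adjusted p, 0.0348). Of 15452 genes 74 passed, 67 higher and 7 lower. Fibrillar matrix genes rose in 3 of 12, mitosis genes in 3 of 12 and S phase genes in 2 of 10, and 1 of 8 quiescence genes fell (8 up, 12 up, 7 up and 4 down adjusted over the list alone, camera adjusted p = 1.59e-07, 1.81e-09, 1.8e-06 and 3.28e-05). An estimated correlation gave an adjusted p of 0.526, 0.526, 0.526 and 0.0729, in that order. The collagen gene Col1a2 rose to 7630 ± 6400 CPM (5.59 ± 1.06). Birc5 rose by 3.06 ± 0.57. Library 1 of day 10 had a profile closest to the pericyte population, and the SD of Col1a2 was of the order of its mean. The count was 0 and 0 without undamaged libraries 1 and 2 and 570 without day 10 library 2, each left out alone. DESeq2 called 783 genes, 599 higher and 184 lower, and the fit of the 5 compared libraries alone 0.

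In FAP at day 10, Tnc, Postn and Cthrc1 were higher than in undamaged muscle. Tnc rose from 45.3 ± 7.54 to 654 ± 384 CPM (SD, n = 3 and 3), a log2 fold change of 3.85 ± 0.68 (SE, adjusted p = 0.0047), Postn reached 4060 ± 2580 CPM (3.10 ± 0.71), and Cthrc1, a collagen regulator of activated fibroblasts, rose by 3.68 ± 0.49 to 172 ± 47.1 CPM. Enpp2, the autotaxin gene, fell from 390 ± 33.4 to 130 ± 12.3 CPM (-1.58 ± 0.30), and Il1r2, a decoy receptor for interleukin 1, by 2.38 ± 0.54 (highest adjusted p of the last 4, 0.0497). Of 15205 genes 53 passed, 47 higher and 6 lower. Fibrillar matrix genes and matrix proteases each rose in 2 of 12 (9 and 9 up adjusted over the list alone, camera adjusted p = 2e-12 and 7.01e-07), Adam12 by 2.63 ± 0.44 and Mmp14 by 1.45 ± 0.29. Under an estimated correlation the adjusted p was 0.00818 and 0.0214, in that order. None of 12 mature myofibre genes passed over all genes (6 up adjusted over the list alone, camera adjusted p = 3.31e-05). Estimating the correlation gave an adjusted p of 0.347. The Wnt-induced gene Wisp1 rose by 3.51 ± 0.61. The count was 204, 25 and 15 without undamaged libraries 1, 2 and 3 and 25, 129 and 29 without day 10 libraries 1, 2 and 3, each left out alone. DESeq2 called 289 genes, 212 higher and 77 lower, and the fit of the 6 compared libraries alone 0.

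In total muscle at day 10, Actc1, Myh3 and Myh8 were higher than before injury. As at day 3, the 2 libraries of each day share a code, so the spread may lie within 1 preparation. Actc1, the cardiac actin gene of regenerating fibres, rose from 98.2 ± 5.24 to 2480 ± 106 CPM (SD, n = 2 and 2), a log2 fold change of 4.66 ± 0.30 (SE, adjusted p = 1.49e-08), and the developmental myosin genes Myh3 and Myh8 rose by 3.25 ± 0.18 and 2.54 ± 0.21. Acta1, skeletal actin, rose from 39000 ± 691 to 72700 ± 4320 CPM (0.90 ± 0.24, adjusted p = 0.00836). Vegfa fell from 330 ± 13.9 to 87.4 ± 0.257 CPM (-1.92 ± 0.31, adjusted p = 0.000254) and Flt1 by 1.03 ± 0.18. Of 14151 genes 4400 passed, 2426 higher and 1974 lower. Myogenic differentiation genes rose in 8 of 10, mature myofibre genes in 3 of 12 and fibrillar matrix genes in 10 of 12 (8, 5 and 10 up adjusted over the list alone, camera adjusted p = 1.93e-05, 0.0303 and 9.38e-05), Col3a1 by 2.01 ± 0.25. This became an adjusted p of 0.468, 0.808 and 0.551, in that order with an estimated correlation. All 6 MHC class II genes and 7 of 9 basement membrane genes rose (6 and 8 up adjusted over the list alone, camera adjusted p = 1.31e-05 and 0.00545), Cd74 to 198 ± 11.5 CPM. The adjusted p was 0.551 for both with an estimated correlation. Igf2 rose to 111 ± 0.377 CPM (2.57 ± 0.18). The count was 2658 and 2407 without undamaged libraries 1 and 2 and 2060 without day 10 library 1, each left out alone.

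In EC at day 10 the test called 0 of 15603 genes (n = 2 and 4), with 737 at an unadjusted p under 0.05 and 43 calls by DESeq2. Over the list alone, 11 of 12 mitosis genes (median log2 fold change 2.56) and 4 of 9 basement membrane genes were higher (camera adjusted p = 6.17e-15 and 0.000176). At an estimated correlation the adjusted p was 0.137 and 0.298, in that order. Without undamaged libraries 1 and 3, each left out alone, the count was 1 and 1.

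In pericytes at day 10 0 of 15127 genes were called (n = 2 and 2), with 187 at an unadjusted p under 0.05 and 44 calls by DESeq2. Of 3 B cell markers, 2 were lower over the list alone (camera adjusted p = 0.00028). The estimated correlation gave an adjusted p of 0.794.

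Between day 1 and day 3, Arg1, Ccl2 and Il1b fell in the CD45+ cells. Arg1, the arginase gene of early wound macrophages, fell from 1020 ± 568 to 7.53 ± 4.19 CPM (SD, n = 4 and 4), a log2 fold change of -7.08 ± 0.91 (SE, adjusted p = 4.54e-05). The monocyte attractant Ccl2 fell from 2020 ± 917 to 71.4 ± 19.9 CPM (-4.82 ± 0.56) and Il1b, interleukin 1 beta, from 2630 ± 818 to 190 ± 87.4 CPM (-3.79 ± 0.51). Gpnmb rose from 710 ± 420 to 9790 ± 2800 CPM (3.79 ± 0.62) and Igf1, insulin-like growth factor 1, by 2.91 ± 0.67 (highest adjusted p of the 4, 0.00673). Vegfa fell from 196 ± 57.6 to 32.9 ± 20.7 CPM (-2.58 ± 0.70, adjusted p = 0.0196). Of 15016 genes 1535 passed, 794 higher and 741 lower at day 3.

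Chemokine genes fell in 7 of 13 and rose in 1, and cytokine genes fell in 5 of 11 (1 up and 8 down and 8 down adjusted over the list alone, camera adjusted p = 1.84e-05 and 5.81e-05). Camera with an estimated correlation gave an adjusted p of 0.268 and 0.277, in that order. The neutrophil attractant Cxcl3 fell by 8.07 ± 1.12. Of 7 neutrophil markers 5 fell, and of 8 inflammatory monocyte markers 4 (7 and 5 down adjusted over the list alone, camera adjusted p = 2.56e-06 and 5.81e-05). For an estimated correlation the adjusted p was 0.134 and 0.0835, in that order. S100a9 fell by 5.66 ± 1.16, Vcan, versican, fell by 4.68 ± 0.48 and the glucose transporter gene Slc2a1 fell by 2.38 ± 0.29, with 3 of 10 hypoxia genes (1 up and 5 down adjusted over the list alone, camera adjusted p = 0.00653). With the correlation estimated, adjusted p = 0.377. All 12 mitosis genes rose (12 up adjusted over the list alone, camera adjusted p = 8.19e-16), Ccnb2 by 3.92 ± 0.50. Adjusted p = 0.0574 with an estimated correlation. Fibronectin, Fn1, fell from 6520 ± 2620 to 997 ± 473 CPM (-2.71 ± 0.64), and the protease gene Mmp19 by 3.36 ± 0.59. Myogenic differentiation genes, outside the gate, rose in 5 of 10 (6 up adjusted over the list alone, camera adjusted p = 1.94e-07). With an estimated correlation, adjusted p = 0.0574. Without day 3 library 2 the count was 962. DESeq2 called 2344 genes.

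Vegfa (chromosome 17, 46016993 to 46032369, minus strand), the main angiogenic growth factor, was followed over all days in every population. In total muscle it stood at 406 ± 17.5 CPM (SD, n = 2 per day) before injury and 48.4 ± 10.8 CPM at day 2, a log2 fold change of -2.94 ± 0.32 (SE, adjusted p = 3.33e-07), and was at 249 ± 26.8 CPM by day 5 and 108 ± 0.325 CPM at day 10. In inflammatory cells it rose from 26.8 ± 11.1 CPM (n = 2) to 224 ± 70.6 CPM (n = 4) at day 1 (3.10 ± 0.95, adjusted p = 0.0265) and was lower again at day 3, at 39.7 ± 25 CPM (n = 4; exact two-sided permutation p between days 1 and 3 = 0.0286, the smallest that 4 against 4 libraries allow). The 1 library at day 10 stood at 256 CPM, above its other day means. In FAP it fell from 124 ± 40.7 CPM (n = 3) to 36.1 ± 8.91 CPM (n = 4) at day 1 (-1.67 ± 0.43, adjusted p = 0.00484) and was 74.4 ± 9.12 CPM (n = 3) at day 10. In MP it stood at 89.8 ± 44.4 CPM (n = 3) before injury, 106 ± 9.24 CPM (n = 2) at day 1 and 18 ± 2.13 CPM (n = 2) at day 3, and in EC between 8.04 and 25.2 CPM on every day. The exact permutation test of FAP at day 3 gave p = 0.0238 (smallest possible 0.0119). At day 3 it gave 0.2 in MP (smallest possible 0.1), and 0.333 in total muscle and pericytes, the smallest possible.

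**Figure D3:**
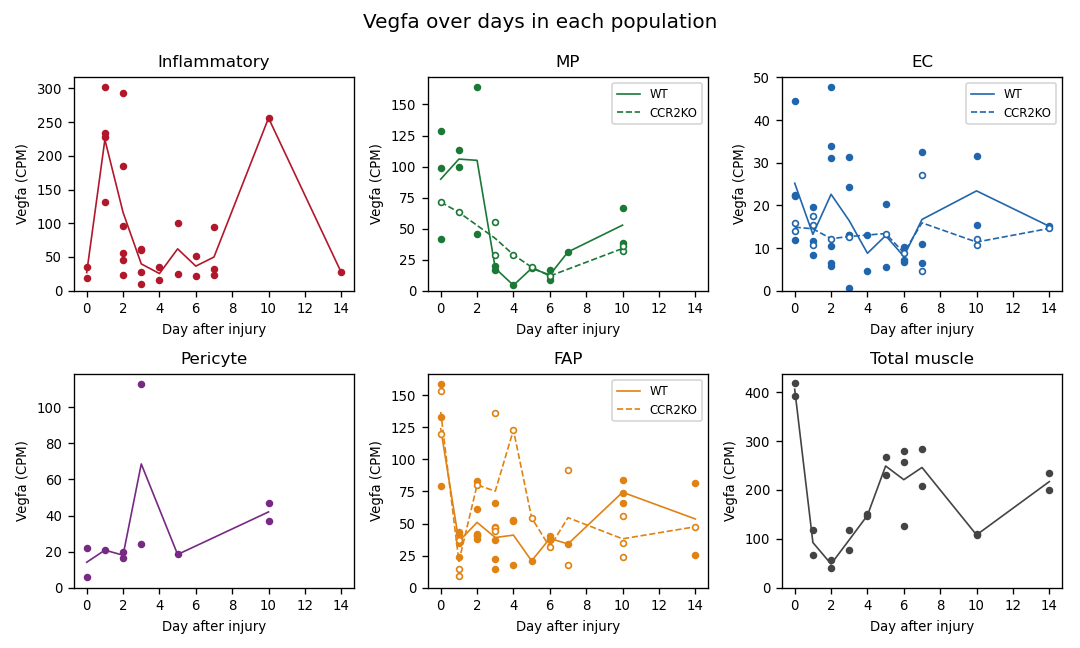
Vegfa in CPM by day after injury, a point per library (filled wild type, open CCR2KO) and lines through the day means. Total muscle starts at 406 CPM, and inflammatory cells reach 224 at day 1 and 256 at day 10 (1 library).

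Calls against undamaged muscle were fewer at day 10 than at day 3. In FAP they numbered 4050 at day 1, 2914 at day 3, 1116 at day 6, 53 at day 10 and 9 at day 14 (n = 4, 6, 3, 3 and 2 against 3), and in total muscle 9497, 9315, 5895, 4400 and 2645 on the same days (n = 2, 2, 3, 2 and 2 against 2). EC calls numbered 848 at day 1, 1020 at day 3, 11 at day 4, 12 at day 5, 172 at day 6 and 0 at day 10 (n = 3, 5, 2, 2, 3 and 2 against 4), MP calls from 2489 at day 1 and 4954 at day 3 to 640 at day 6 and 74 at day 10 (n = 2 each against 3). Inflammatory cells gave 2872 calls at day 1, 4934 at day 2, 1033 at day 4, 1615 at day 6 and 249 at day 7 (n = 4, 6, 2, 2 and 3 against 2). Library number differs between days in FAP, EC and inflammatory cells, and the difference between days was not tested.

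**Figure D4:**
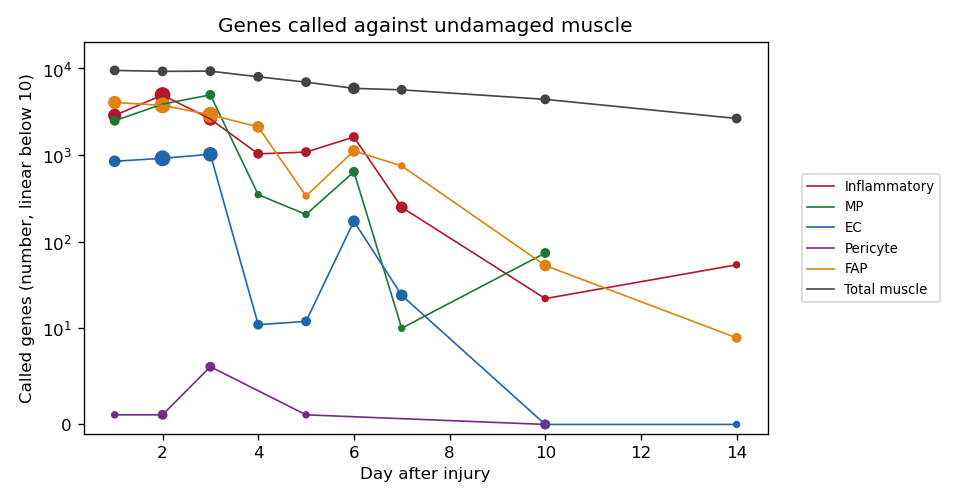
Number of genes called against undamaged muscle (log scale above 10) by day after injury, with point area in proportion to the libraries of that day. Total muscle has 2645 called genes at day 14, from libraries that share a code, and EC reach 0 at day 10.

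The CCR2KO series compared sorted cells of knockout and wild-type mice, since loss of the receptor limits monocyte entry into damaged muscle. In FAP at day 3, leukocyte genes were lower and Ccl2, Csf1 and Ereg higher in CCR2KO. Tyrobp, an adaptor of myeloid receptors, fell from 28.3 ± 22.4 CPM in wild type to 0.497 ± 0.186 CPM in CCR2KO (SD, n = 6 and 3), a log2 fold change of -5.88 ± 0.84 (SE, adjusted p = 0.000135). C1qb fell by 5.91 ± 0.98 and Cd74 by 3.78 ± 0.76 (highest adjusted p, 0.00329). Ccl2, a ligand of CCR2, was 951 ± 707 CPM in CCR2KO against 124 ± 45.4 CPM (2.94 ± 0.56, adjusted p = 0.0019). Csf1, the macrophage growth factor, rose by 1.19 ± 0.26 to 899 ± 214 CPM, and Ereg, an epidermal growth factor receptor ligand, rose by 4.39 ± 1.00. Of 15391 genes 278 passed, 112 higher and 166 lower in CCR2KO.

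Of 6 leukocyte markers 5 fell, of 6 MHC class II genes 4 fell, and of 12 macrophage markers 7 fell and 1 rose (6 down, 5 down and 1 up and 9 down adjusted over the list alone, camera adjusted p = 7.24e-20, 3.55e-09 and 1.65e-13). An estimated correlation gave an adjusted p of 0.000114, 0.0228 and 0.00565, in that order. Growth factor genes rose in 2 of 14 (5 up adjusted over the list alone, camera adjusted p = 0.000244), Pdgfa of the platelet-derived family by 1.37 ± 0.37. Under an estimated correlation the adjusted p was 0.239. Cytokine genes rose in 3 of 11 (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.542), Lif, leukaemia inhibitory factor, by 2.59 ± 0.63. The matrix gene Tnc rose from 562 ± 244 to 2430 ± 1220 CPM (2.11 ± 0.53) and Slc2a1, the glucose transporter gene, by 1.78 ± 0.32. Vegfa stood at 74.7 ± 54.7 against 36.9 ± 17.7 CPM (1.01 ± 0.47, adjusted p = 0.378). Without CCR2KO day 3 libraries 1, 2 and 3, each left out alone, the count was 146, 155 and 103. DESeq2 called 510 genes.

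**Figure D5:**
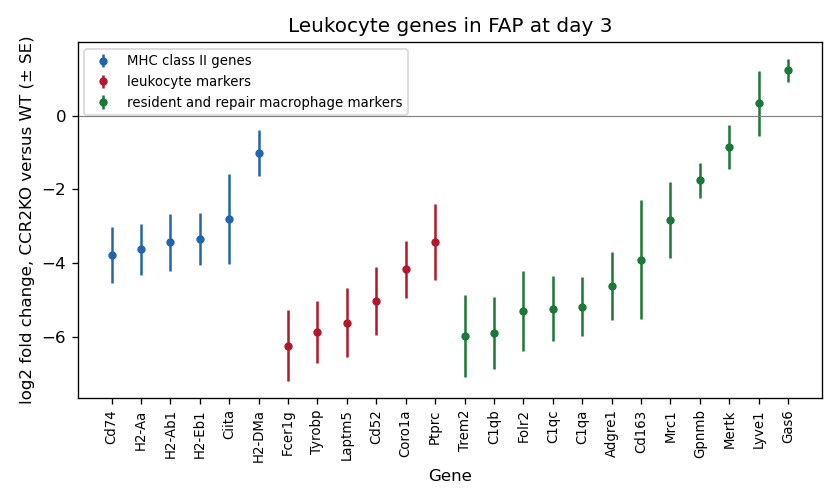
Log2 fold change of leukocyte, macrophage and MHC class II genes in FAP at day 3, CCR2KO against wild type (points, with SE as bars; 3 and 6 libraries). All 6 leukocyte markers lie below 0, and Gas6 lies above it.

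The difference between the genotypes in the change from undamaged to day 3 was also tested itself, and 55 of 15391 genes passed, 1 higher and 54 lower in CCR2KO. The lysosomal protease gene Ctss showed a difference of -8.71 ± 1.34 on the log2 scale (SE, adjusted p = 0.00114), Tyrobp of -7.68 ± 1.18 and Cd74 of -6.54 ± 1.10, and Tnfrsf12a, the TWEAK receptor gene, was the gene higher in CCR2KO, where it rose from 18.5 to 93.1 CPM while it fell from 45 to 23.2 CPM in wild type (3.27 ± 0.60, adjusted p = 0.00329). Part of these lower responses is a higher level in CCR2KO before injury (n = 2 against 3), of 16.2 against 1.97 CPM for Ctss, 2.01 against 0.502 for Tyrobp and 29 against 4.26 for Cd74. Lower responses were called for 5 of 6 leukocyte markers, 4 of 12 macrophage markers, 0 of 8 T and NK cell markers and 4 of 6 MHC class II genes (6, 7, 5 and 6 down adjusted over the list alone, camera adjusted p = 2.06e-23, 1.74e-13, 6.72e-07 and 1.99e-16). Estimating the correlation gave an adjusted p of 2.87e-05, 0.0041, 0.016 and 0.00118, in that order. The count was 30 without CCR2KO day 3 library 2, 15 without CCR2KO undamaged library 1 and 34 and 30 without wild-type undamaged libraries 2 and 3, each left out alone. It was 111 by DESeq2 and 0 without libraries of code R52, which leave 1 undamaged wild-type library.

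At day 10, the matrix genes Acan and Smoc1 were higher and Prg4 lower in FAP of CCR2KO. The cartilage proteoglycan aggrecan, Acan, rose from 4.1 ± 2.17 CPM in wild type to 141 ± 34 CPM in CCR2KO (SD, n = 3 and 3), a log2 fold change of 5.10 ± 1.14 (SE, adjusted p = 0.0334), and the matricellular gene Smoc1 rose by 3.96 ± 0.67 to 109 ± 14 CPM. Adam12 rose from 83.6 ± 59.8 to 511 ± 166 CPM (2.61 ± 0.49) and the Wnt modulator genes Sfrp1 and Rspo2 by 2.41 ± 0.43 and 4.02 ± 0.93. Prg4, lubricin, fell from 539 ± 96.1 to 92.8 ± 41.6 CPM (-2.54 ± 0.52) and Hsd11b1, which activates glucocorticoids, by 2.33 ± 0.51 (highest adjusted p of the last 6, 0.0422). Of 15391 genes 52 passed, 33 higher and 19 lower in CCR2KO. Matrix proteases rose in 2 of 12, and none of 12 fibrillar matrix genes passed over all genes (6 up and 1 down and 8 up adjusted over the list alone, camera adjusted p = 4.4e-05 and 9.43e-09). This became an adjusted p of 0.0907 and 0.0796, in that order with an estimated correlation. The count was 11 and 6 without CCR2KO day 10 libraries 1 and 3 and 14, 0 and 25 without wild-type day 10 libraries 1, 2 and 3, each left out alone. It was 0 without libraries of code R52 (1 CCR2KO and 1 wild type at day 10), 7 with the compared groups alone, 24 with the replicate number as a block, 107 without CCR2KO day 7 library 1 and 223 by DESeq2.

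Averaged over the days sampled in both genotypes, 4 of 13 chemokine genes were higher in FAP of CCR2KO. Ccl2 rose by 1.65 ± 0.37 (log2 fold change, SE, adjusted p = 0.00896, with 18 CCR2KO and 32 wild-type libraries), Ccl7, another CCR2 ligand, by 1.30 ± 0.29, and Cxcl5, a neutrophil attractant, by 2.40 ± 0.52. The acute-phase gene Saa3 rose by 3.45 ± 0.58 and Tnc by 1.40 ± 0.26 (highest adjusted p of the last 4, 0.00778). Of 14654 genes 313 passed, 172 higher and 141 lower. The chemokine list was not called (6 up and 1 down adjusted over the list alone, camera adjusted p = 0.0588). Growth factor genes rose in 3 of 14 and S phase genes in 4 of 10 (5 and 6 up adjusted over the list alone, camera adjusted p = 2.47e-05 and 9.35e-06), Ereg by 2.46 ± 0.58 and Mcm5 by 0.88 ± 0.25. The adjusted p was 0.212 for both with an estimated correlation. The complement gene C7 fell by 1.49 ± 0.39 and the collagen gene Col4a1 by 0.60 ± 0.17. Of 8 inflammatory monocyte markers, a list that holds Ccr2, 3 fell (2 up and 3 down adjusted over the list alone, camera adjusted p = 0.00376). At an estimated correlation the adjusted p was 0.212. None of 6 leukocyte markers passed over all genes (0 adjusted over the list alone, camera adjusted p = 5.6e-05). The estimated correlation gave an adjusted p of 0.215. Alad, of haem synthesis, and Ide, the insulin-degrading enzyme gene, rose by 1.00 ± 0.22 and 0.96 ± 0.13 (adjusted p = 0.00723 and 1.55e-05). Vegfa differed by 0.28 ± 0.23 (adjusted p = 0.617). With 1 library left out at a time, the count was 195 without CCR2KO day 5 library 1 or wild-type day 5 library 1, 164 without CCR2KO day 4 library 1 and 163 without CCR2KO day 6 library 1. DESeq2 called 714 genes, 315 higher and 399 lower. Without the libraries whose code in the labels holds R52 (2 CCR2KO, 15 wild type) the count was 196, without those whose code names another day than the title 76, and with the replicate number as a block 14.

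In EC averaged over days, 12 of 15050 genes passed, 8 higher and 4 lower in CCR2KO (14 CCR2KO and 29 wild-type libraries). Alad rose by 1.46 ± 0.22 (log2 fold change, SE, adjusted p = 0.00039) and Pgf, placental growth factor, by 1.07 ± 0.23 (adjusted p = 0.0465). Lars2, the mitochondrial leucyl-tRNA synthetase gene, fell by 1.00 ± 0.15 (adjusted p = 0.00039). Eno1b, an enolase gene that can share reads with near-identical Eno1, fell by 3.37 ± 0.70. None of 8 satellite cell markers passed over all genes (2 down adjusted over the list alone, camera adjusted p = 0.00403). With an estimated correlation, adjusted p = 0.652. Vegfa differed by -0.28 ± 0.33 (adjusted p = 0.719). With 1 library left out at a time, the count was 6 without CCR2KO undamaged library 1, day 2 library 1, day 5 library 1, wild-type day 1 library 3 or 1 of the 2 unnumbered wild-type day 5 libraries, 5 without CCR2KO day 1 library 3, day 6 library 1 or wild-type day 1 library 1 and 4 without CCR2KO day 14 library 1 or wild-type day 14 library 1. DESeq2 called 227 genes, 85 higher and 142 lower. Without R52 libraries (1 CCR2KO, 12 wild type, not an unnumbered day 5 library) the count was 1.

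In MP averaged over days, Alox5, the 5-lipoxygenase gene of leukotriene synthesis, was the gene called (1 of 14634). It rose by 2.33 ± 0.28 in CCR2KO (adjusted p = 0.00168, with 9 CCR2KO and 13 wild-type libraries). It is 1 of the genes enriched in inflammatory cells. None of 11 immediate early and heat shock genes or of 12 mitosis genes passed over all genes (7 down and 8 up adjusted over the list alone, camera adjusted p = 2.93e-08 and 5.71e-06). For an estimated correlation the adjusted p was 0.311 for both. With 1 library left out at a time, the count was 6 without CCR2KO day 1 library 1 and 2 without CCR2KO day 10 library 2 or wild-type day 1 library 1. Without libraries of code R52 (1 CCR2KO, 8 wild type) the count was 0, and DESeq2 called 324 genes, 142 higher and 182 lower.

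In EC at day 1 the test called 0 of 15860 genes (n = 3 and 3), with 456 at an unadjusted p under 0.05 and 21 calls by DESeq2. None of 9 pericyte and smooth muscle markers was called (0 adjusted over the list alone, camera adjusted p = 0.000697). With the correlation estimated, adjusted p = 0.758.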

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

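The tests of leukocyte RNA in the FAP and MP gates and of the genes near Ccr2 were chosen after the results were seen, and the counts over other splits of the libraries were planned.

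The response of FAP to injury at day 3 differed between the genotypes by a test of the difference itself, with 55 genes called and 54 of them lower in CCR2KO. Of the 166 genes lower in CCR2KO at day 3, 137 (82.5%) were among those enriched in the inflammatory libraries, against 16.1% of all tested genes. Fewer leukocytes, or less of their RNA, in the FAP gate of CCR2KO muscle may account for these genes, although the gate removes CD45+ cells, and Tyrobp stood at 28.3 ± 22.4 CPM in wild-type FAP at day 3 (SD, n = 6). Fewer leukocytes can only lower genes, so the share among the 112 genes higher in CCR2KO, 25 (22.3%), decides nothing, and these genes stay open. Whether leukocyte RNA was inside sorted cells, attached to them or free was not tested, and expression of these genes by FAP themselves stays open.

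In MP at day 3 all 6 leukocyte markers were higher than in undamaged muscle, and library 1 of that day had a profile closest to the inflammatory libraries. Without the libraries closest to another population, which leaves 1 library at day 3, 5 of the 6 markers were still called, with a median log2 fold change of 6.45 against 8.15. This argues against that library as the whole source, and leukocyte RNA in both libraries of that day may be a source of the shared part, which was not tested further. The gate removes CD45+ cells. No biological explanation was tested.

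Across days, Lars2, which lies 0.74 Mb from Ccr2 on chromosome 9 (123366927 to 123462666), was lower in CCR2KO in FAP (log2 fold change -0.93 ± 0.16, SE, adjusted p = 0.000497) and EC (where it fell by 1.00 ± 0.15, adjusted p = 0.00039), and Ccr9, 0.42 Mb away, in FAP (-2.95 ± 0.72). A segment of another strain around the targeted gene could lower such neighbours, but 3 calls within 10 Mb over the 3 populations against 1.78 expected by position do not decide it, and among genes at p < 0.001 the one-sided Fisher's exact p was 0.499 in FAP, 0.361 in EC and 0.286 in MP. Away from that segment, Alad on chromosome 4 (62509169 to 62519918) and Ide on chromosome 19 (37268743 to 37337852) were higher in CCR2KO in FAP and EC, Ide at 102 ± 37.3 against 54 ± 18.9 CPM in FAP (SD, n = 18 and 32). Copy number at both genes is known to vary among laboratory mice, so a difference in strain background stays open beside an effect of the receptor, and neither was tested on sequence.

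Of 36 tests for a single library far from its group, over 4 measures, 5 found one, where chance finds about 1 in 20. Reads in no feature made up 24.1% in EC day 2 library 1 (4.4% to 9.1% in the other libraries of the group) and 19.6% in EC day 3 library 2 (4.7% to 8.4%). They made up 15.2% in FAP day 2 library 1 (3.8% to 5.2%) and 9.2% in FAP day 3 library 2 (4.9% to 6.5%). The proliferation gene Mki67 stood at 190 CPM in EC day 3 library 5, against 18.1 to 47.7 CPM in the other 4. Only wild type was tested.

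Other splits of the same libraries into groups of the same sizes gave a measure of chance. For FAP at day 3, 1 of 84 splits (the real one, 2914 calls) gave as many genes and the highest other gave 828. That share is under 0.05 and the smallest these splits can give, so it does not exclude chance. The same holds for inflammatory cells at day 3 against day 1 (1 of 35 splits, 1535 against 0), FAP of CCR2KO across days (1 of 100, 313 against 4) and at day 3 (1 of 84, 278 against 6). It holds for the enriched genes too, with 1 of 40 splits each and a real and highest other count of 2932 and 768 in inflammatory cells, 1747 and 1463 in MP, 2518 and 1395 in EC, 2157 and 12 in pericytes and 3014 and 1365 in FAP. For MP of CCR2KO across days, 1 of 100 splits, the real one, called 1 gene and the others 0, and with the R52 code as a covariate the real one called 0. For EC at day 3, 4 of 100 splits gave at least the real 1020. The highest other, 1318, again set the 4 undamaged libraries against day 3, with day 3 library 5, closest to FAP, moved across. For EC of CCR2KO across days, 4 of 100 gave at least the real 12, and the highest other gave 354. Both shares are under 0.05, but a split with 354 calls points to structure in these EC libraries other than genotype. That split did not follow the R52 code (3 of 14 libraries against 10 of 29, an unnumbered library uncounted). With 3 against 3 libraries, 10 splits are too few for a share under 0.05. Counting splits with at least the real number, there were 2 for FAP at day 10 (53, highest other 85), 1 for FAP of CCR2KO at day 10 (52 against 0) and 10 for EC of CCR2KO at day 1 (0 and 0). The split with 85 calls in FAP at day 10 is the R52 code itself (0 of 3 libraries against 3 of 3). With that code as a covariate the real split called 69.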

How the results depend on the processing

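Leaving out libraries under 2000000 counts or over 40% outside genes, libraries closest to another population, and CCR2KO libraries with 1 CPM of Ccr2 or more, and adding Xist as a covariate, were chosen after seeing the data. The cause of a moved count was not tested, except that fits of the compared groups alone and fits without libraries rest on fewer samples. Several groups hold 2 libraries, and the lowest depth, 1236809 counts, is in pericytes at day 3. No direction of a named gene turned in any call: of 4149 values for 199 named results under alternatives, 3724 stayed on their side of the threshold, 424 lost the call with the same direction and 1 gained it, Vegfa in pericytes at day 3 without day 3 library 2 (3.07). Of 230 counts under settings other than single libraries, 168 lay within 1.5 times the reported one and 62 did not, and of 98 counts per day 64 did and 34 did not. The number of ligands with more than 1 source, 103, ran from 90 to 151. A preparation block, with 84 libraries in 35 preparations (estimated correlation 0.323), was run in limma for the comparisons whose codes allow it.

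With DESeq2, calls numbered 1909 for EC, 834 for pericytes at day 3, and at day 10 783 for MP, 43 for EC, 44 for pericytes and 289 for FAP. They numbered 2344 for inflammatory cells at day 3 against day 1. In CCR2KO against wild type DESeq2 gave 714 in FAP, 227 in EC and 324 in MP across days, 510 and 223 in FAP at days 3 and 10, 21 in EC at day 1, and 111 for the response at day 3. It shared all 74 calls of MP at day 10 and 303 of the 313 of FAP across days. With RLE scaling pericytes at day 3 had 39. Without a filter on low counts the count was 102 for pericytes at day 3, 229 for MP and 1 for pericytes at day 10, and 6 for EC and 3 for MP of CCR2KO across days.

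With the R52 code as a covariate the count was 2793 for MP and 44 for pericytes at day 3, 128 for MP and 3 for EC at day 10, and 5 for EC and 0 for MP of CCR2KO across days. Without R52 libraries it was 196 in FAP, 1 in EC and 0 in MP of CCR2KO across days, 0 in FAP at day 10 and 0 for the response at day 3. Without libraries whose code names another day it was 76 in FAP and 0 in MP of CCR2KO across days, and 34 in FAP at day 10. With the compared groups alone it was 1429 for inflammatory cells, 258 for EC and 27 for pericytes at day 3, 0 for MP and 0 for FAP at day 10, 7 for FAP of CCR2KO at day 10 and 20 for the response.

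Without libraries under 2000000 counts or over 40% outside genes the count was 593 for MP and 380 for pericytes at day 3, 0 for MP at day 10 and 6 for EC of CCR2KO across days. Without libraries closest to another population it was 2021 for EC at day 3, and 210 for MP and 3 for EC at day 10. Without CCR2KO libraries with 1 CPM of Ccr2 or more it was 2 for MP across days and 107 for FAP at day 10. With Xist as a covariate it was 508 for inflammatory cells and 0 for pericytes at day 3, 192 for MP, 96 for FAP and 7 for pericytes at day 10, and 19 for MP of CCR2KO across days.

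With the replicate number as a block the count was 16 for pericytes at day 3, 46 for MP at day 10, 14 for FAP, 4 for EC and 0 for MP of CCR2KO across days, and 24 for FAP of CCR2KO at day 10. The numbers do not pair the libraries: the deviations of same-numbered libraries had a median correlation of -0.004 over 389 pairs, against 0.001 over 992 other pairs.

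With each library left out in turn, the lowest and highest counts at day 3 were 727 and 3031 for inflammatory cells, 2130 and 4201 for MP, 263 and 1602 for EC, 0 and 6727 for pericytes, 1603 and 2944 for FAP and 7841 and 8915 for total muscle. At day 10 they were 0 and 570 for MP, 0 and 1 for EC, 0 and 0 for pericytes, 15 and 204 for FAP and 2060 and 3518 for total muscle. They were 962 and 1429 for inflammatory cells at day 3 against day 1. In CCR2KO they were 163 and 407 for FAP, 4 and 17 for EC and 1 and 6 for MP across days, 103 and 293 for FAP at day 3, 0 and 44 for FAP at day 10, 0 and 0 for EC at day 1 and 15 and 62 for the response. For enriched genes they were 2820 and 3027 in inflammatory cells, 1307 and 1736 in MP, 2381 and 2593 in EC, 1072 and 2296 in pericytes and 2811 and 3296 in FAP. Where this leaves 1 library in a group, the lone sample is assumed to vary like the other groups.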

Other observations

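The genes below were chosen after their values were seen, and levels by day are given without a test. Total muscle showed an order of transcripts after notexin. Myeloid genes were high at day 1, when Arg1 stood at 92.7 ± 14.1 CPM (SD, n = 2 at each of these days), against 1.02 ± 0.768 at day 3, and S100a9, a neutrophil calgranulin gene, at 33.7 ± 16.4 CPM. The macrophage gene Adgre1 was highest at day 2, at 195 ± 12.3 CPM, and the proliferation gene Mki67 at day 3, at 86.1 ± 18.7 CPM against 1.43 ± 0.174 before injury. Ckm, at 34200 ± 116 CPM before injury and 8990 ± 1340 at day 1, was at 53300 ± 2520 CPM by day 10.

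The glial gene Sox10 was found in every library of the pericyte gate. It lay between 70.8 and 1360 CPM in the 10 pericyte libraries (median 312), with a median of 8.03 CPM in MP (16 libraries), 1.22 in EC (31) and 0.137 in FAP (32). NG2 is also made by glial cells, and which cells of the gate held this transcript was not tested.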
